A study of Macaca fascicularis with 102 samples.

How the data were processed

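RNA was extracted from the cultured cells and 25 ng was taken into a Lexogen QuantSeq forward 3' library, per the labels' protocols. Cells had been cultured with the stimulus for about 24 hours. The labels give the peptide concentration as 3 mg/mL for each peptide, a unit that could not be checked here. Salmon, given as version 14.0, is named in the submitters' processing notes. The genome build and annotation are not given in the sources used here.

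The authors deposited 1 table of whole-number counts per gene for the whole series. Its 102 columns of counts were not used in any result, because 0 of their names occur in a title, description or other label of the 102 samples. Column order and column values were not used to assign samples. When the file was first inspected, column totals and the most abundant genes were looked at to identify the unit, and these values entered no result.

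The groups were taken from the sample titles. The design fixed before the data were examined comprised 7 comparisons tested per gene and tests of 26 gene lists, 12 of them cell type markers. It also held permutation tests of an interferon gamma response score and a set of processing alternatives. A further part was the overlap of the AAV9 peptide and anti-CD3 responses at the time point coded nec. None of these was run. The header and the gene names of the table were read with Python 3.11.15. Of the 15494 row names without a numbered suffix, 14047 were identical to a gene symbol of the RefSeq annotation of a cynomolgus assembly, which was used for names only. A list gene was counted as having a row when its symbol, or an alias fixed in advance, was identical to a row name.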

Results

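Peripheral blood mononuclear cells of cynomolgus monkeys were cultured with a stimulus and profiled by 3' RNA sequencing, an assay that reads the 3' end of each polyadenylated transcript. The series asks what cell-mediated immune response the capsid of AAV9, an adeno-associated virus used as a gene therapy vector, draws from these cells. Blood was taken before the animals were treated with AAV9 or 14 days afterwards. Cells were then exposed to DMSO as the negative control, to a pool of AAV9 capsid peptides, or to an antibody against CD3 as the positive control. Anti-CD3 stimulates T cells through the T cell receptor complex whatever their specificity.

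The labels divide the samples into 6 groups, from 3 stimuli and 2 time points coded pid and nec. DMSO has 15 samples at pid and 18 at nec. The AAV9 peptide pool has 18 samples at pid and 18 at nec. Anti-CD3 has 15 samples at pid and 18 at nec. The labels do not state which code stands for the samples taken before treatment. Replicate numbers recur across the groups, but the labels do not state that a number marks an animal.

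The design implies a comparison of AAV9 peptides with DMSO at each time point, of anti-CD3 with DMSO at each time point, and of the time points in DMSO. It also implies a test of whether each stimulus response differs between the time points. No expression value, fold change or test is reported for any of these 7 comparisons. They were planned with no term for the animal, so each library would have been treated as independent. The columns of the count table carry laboratory codes, and 0 of these codes occur in the sample labels used here. A key from the codes to the samples would allow every comparison to be made between the groups as coded, but no such key was among the sources used here. Without it, a column could be tied to a sample only by its position in the table or by its own values. The codes run consecutively and are as many as the samples, but the sources used here do not state that the columns follow the order of the samples, so position was not used. Assigning a column to anti-CD3 because its activation genes were high would fix the outcome of the comparison in advance. The depth of each group is therefore not given either.

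The gene names of the table can be read without assigning columns to samples and were examined. The table has 21569 gene rows, of which 6075 carry a name with a numbered suffix. All 10 readouts fixed before the data were examined have a row. They are the cytokines IFNG, IL2 and TNF, the cytotoxic protease GZMB, the activation receptors IL2RA and TNFRSF9, the interferon-induced chemokines CXCL9, CXCL10 and CXCL11, and IDO1, an interferon-induced enzyme of tryptophan breakdown. All 24 genes of the T cell activation list have a row, as do 15 of 24 T cell cytokines and chemokines and 18 of 20 cytotoxic genes. The interferon gamma response list has a row for 26 of 37 genes, and the type I interferon list for 27 of 33. Among cell type markers, 14 of 17 T cell genes, 14 of 16 B cell genes, 10 of 13 NK cell genes and 18 of 20 monocyte genes have a row. Coverage was lowest for glycolysis, with 10 of 20 genes, and for erythroid markers, with 7 of 12. Next came plasma cell markers, with 6 of 10, and then the T cell cytokines and chemokines given above. These counts describe which gene names are listed under the symbols or aliases searched, and not whether any gene was expressed.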

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

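No paired analysis was possible because the columns of the count table carry no replicate number, group or sample name that the labels hold. Even with a key, pairs would stay undefined, because the labels do not state that a replicate number marks an animal. The other normalizations, filters, tests and choices of libraries laid out before the data were examined were not run, because no column could be tied to a sample. Nothing can be said of how any of the 7 comparisons depends on the processing. The counts of gene names were repeated with matching rules chosen after seeing the data. Leaving out the aliases changed the count of 0 of 26 lists, and ignoring case and numbered suffixes changed 0 of 26. Removing the suffixes left 14047 names identical to an annotated symbol. Since these rules moved none of the counts, they are no evidence of stability beyond the matching of names.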
